A study of Caenorhabditis elegans with 3 samples.

How the data were processed

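The series holds 3 arrays of total RNA from young adult Caenorhabditis elegans hermaphrodites, taken at 0 h without nanotubes and after 4 h and 24 h with multiwall carbon nanotubes at 1 mg/L. Per the labels' protocols, RNA was isolated with a column kit and labelled from the 3' end by in vitro transcription for an Affymetrix C. elegans array. The deposited values are normalized probe set intensities on a linear scale, 1 column per array, running from 9.08 to 31806. Per the submitters' processing notes, RMA, MAS5 and Affymetrix Expression Console 1.1 were used, and the role and order of these tools are not given in the sources used here. The values themselves show similar medians on all arrays and exact ties, with 27.8% of probe sets identical at 4 h and 0 h, 18.0% at 24 h and 0 h and 22.2% at 24 h and 4 h. Such ties lower the apparent noise, and 14.7%, 6.7% and 11.0% of the genes analysed had a ratio of exactly 0 in these comparisons.

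Of the 22625 probe sets, 77 are controls, 20766 are annotated to 1 gene, 887 to several genes and 895 to none. Gene symbols came from the array's annotation table, and 20701 of the 20766 were matched through the gene ID to a current gene table of the WBcel235 assembly, used for names and no coordinates. Probe sets of several genes or none were left out of the gene results. Intensities had 32 added and were put on the log2 scale. Probe sets whose mean over the arrays reached the median of all probe sets (log2 value 7.09, an intensity of 103.9) were kept, and each gene was represented by its brightest probe set, giving 8634 genes of 17138. Probe sets named _x_ or _s_ by the manufacturer can hybridise with other transcripts and were marked. The background floor was the highest intensity of a control for absent transcripts, 67.83, and ratios with 1 value under it are given as "at least" a fold against the floor, computed with 32 added. They make up 31 of 429 genes past 2-fold at 4 h against 0 h, 118 of 1146 at 24 h against 0 h and 53 of 475 at 24 h against 4 h.

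Samples were grouped by exposure time, and 3 comparisons were made: 4 h with 0 h, 24 h with 0 h and 24 h with 4 h. With 1 array per group no test across replicates exists, so genes are described by a 2-fold threshold without p-values. The median of each of 44 gene lists was placed among 10000 random lists of the same size, matched on deciles of mean expression, which describes these arrays and not the conditions. The technical SD of a ratio was taken from 1830 genes with 2 or more passing probe sets, as the root mean square difference between a pair of them divided by the square root of 2, after the plain SD about the mean was seen to leave out a systematic part. The lists, the 2-fold threshold, the filter and the alternatives were fixed before the data were examined. So was the rule for named genes. It takes the 10 highest and 10 lowest genes of each comparison with 0 h, 5 at either end for 24 h against 4 h, up to 4 members of each list with the largest ratio per comparison, and all reference genes. The floor and the scaling on hybridisation controls were chosen after the data were seen.

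Alternatives were thresholds of 1.5-fold and 3-fold, quantile normalization, centring on the median, removal of a loess trend of the ratio on the mean (span 0.3), and subtraction of the 1st percentile with 16 added. Others were no filter, a filter at the 75th percentile, the mean of all probe sets of a gene, leaving out _x_ and _s_ probe sets, and pseudocounts of 1 and 100. Scaling on the bioB, bioC, bioD and cre controls, the dimmest probe set per gene, and counts without sperm and collagen genes were added later. The overlap of calls was set against 100 simulations of unchanged arrays, once with each comparison's own technical SD and their covariance and once with the larger SD in both.

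The scripts were tested on simulated arrays with 200 genes changed by known folds and noise of the measured technical SD. That SD covers probe sets within an array and not differences between animals, cultures or hybridisations. The shares called in these simulations are therefore no error rates for unchanged worms. The noise was drawn evenly in both directions, so the lower ratios of brighter probe sets were not simulated. For 4 h against 0 h (8637 genes), 24.0% of genes changed 2-fold, 100.0% of those changed 3-fold and 0.00% of unchanged genes were called higher or lower by 2-fold. For 24 h against 0 h (8633 genes), 42.6% of genes changed 2-fold and 79.2% of those changed 3-fold were called in the right direction, and 1.88% of unchanged genes were called higher and 1.73% lower. Of 200 simulated lists of 20 unchanged genes, 4.5% lay outside the random range for 4 h and 7.0% for 24 h. These lists were drawn from the same genes as the random lists, so a small share was fixed by construction. It checks the computation and does not cover lists of related genes. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.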

Results

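Gene expression was measured in young adult hermaphrodites of the wild-type N2 strain of the nematode Caenorhabditis elegans before and during exposure to multiwall carbon nanotubes, which are hollow fibres of rolled carbon sheets. The exposure used 1 mg/L of nanotubes in K-medium, a salt solution in which worms are kept for toxicity tests. Total RNA from 0 h, 4 h and 24 h was hybridised to 1 Affymetrix array each, giving 3 arrays with 22625 probe sets. Median intensities were 101.8 at 0 h, 100.2 at 4 h and 102.8 at 24 h, and 57.6%, 57.3% and 57.9% of probe sets lay above the brightest control for absent transcripts. With 1 array per time there were no replicates, and the number of arrays limits the precision of every value. No unexposed array at 4 h or 24 h was part of the series, so the exposure, the time in the medium and the age of the worms change together in every comparison. Ratios are log2 ratios of intensities with 32 added, which understates changes of dim genes, and "higher" or "lower" means at least 2-fold unless a value is given.

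The comparison of 4 h with 0 h asked which transcripts differed early in the exposure. The genes mtl-1 and ftn-1, for metal and iron binding, were far higher at 4 h, and 23 of the 87 detoxification enzyme genes of 3 lists were lower, with 7 higher. The metallothionein gene mtl-1, whose product binds metal ions, was at an intensity of 3165 against 177 at 0 h (log2 ratio 3.94). The ferritin gene ftn-1, which serves iron storage, was at 4899.7 against 518.7 (3.16), and the other metallothionein gene, mtl-2, was at 6866 against 3419 (1.00). The UDP-glycosyltransferase gene ugt-13 was at 146.8 against 1959.7 (log2 ratio -3.48), and the glutathione S-transferase gene gst-4 was at 107.2 against 981.2 (-2.86).

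Of the 8634 genes measured, 148 were higher and 281 lower at 4 h. Besides mtl-1, ftn-1 and ugt-13, the 10 highest and 10 lowest genes included scl-2, which encodes a secreted CAP-domain protein (log2 ratio 3.83), the cytochrome P450 gene cyp-37B1 (3.12) and the mitochondrial transhydrogenase gene nnt-1 (2.68). They also included fmo-1, which encodes a flavin monooxygenase (2.44), and the uncharacterised genes ZC395.5 (2.62), C50F7.5 (2.59), F43C11.7 (2.51) and Y6E2A.4, which was at least 4.10-fold higher. At the lower end were cyp-35C1 (-2.88), ugt-8 (-2.78), the C-type lectin gene clec-265 (-2.54), Y16B4A.2 (-2.87) and F21C10.9 (-2.71). Values at 4 h under the background floor put ugt-63 at least 5.65-fold lower, nspe-1 at least 5.88-fold lower and hsp-70 at least 5.07-fold lower.

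Among the detoxification lists, 13 of 37 UDP-glycosyltransferase genes were lower and 3 higher (median log2 ratio -0.58), among them ugt-22 (-2.51) on the lower side and ugt-31 (1.47) on the higher. Of 23 glutathione S-transferase genes, 6 were lower and 1 was higher (median -0.27). The lower members included gst-26 (-2.45), gst-5 (-2.01) and gst-10 (-1.79), and the higher one was gstk-2 (1.00). Of 27 cytochrome P450 genes, 4 were lower and 3 higher (median -0.11). The cyp-35 subfamily, known to respond to foreign compounds, held cyp-35A4 (-1.92) and cyp-35A5 (-2.50) on the lower side. The medians of these 3 lists lay below the 2.5 percentile of 10000 random lists of the same size and brightness. For the cytochrome P450 list this ended without a filter (percentile 49.9) and with a filter at the 75th percentile (18.9). Of 23 oxidative stress genes, 4 were lower and 0 higher (median -0.03), including nit-1 (-1.52) and msra-1 (-1.01). Of 26 ABC transporter genes, 1 was lower, pmp-5 (-1.11). In the 4 h array the 5' to 3' signal ratios of 4 of 4 control transcripts were higher than at 0 h, by a median of 0.32 on the log2 scale. The brighter of a gene's probe sets had lower ratios than the dimmer in 75.6% of 1830 genes, with a mean difference of -0.17 (SE 0.007).

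Genes known to follow the transcription factor DAF-16, which is active when insulin signalling is low, had a median of 0.54, above the random lists. In this list 5 of 18 genes were higher and 1 was lower. The higher ones included mtl-1, ftn-1, nnt-1 and the small heat shock gene hsp-12.6 (1.49), and the lower one was hsp-16.2. Of 17 heat shock genes, 4 were lower at 4 h. The small heat shock gene hsp-16.2 was at 66.27 against 465.8 at 0 h, at least 4.99-fold lower, and hsp-16.41 was at least 2.56-fold lower. Both were again near their 0 h level at 24 h, at 414.1 and 216.9. Of 14 metal response genes, 2 were higher, mtl-1 and ftn-1, and 1 was lower, the cadmium-responsive gene cdr-4 (-2.04). The ratio of mtl-2 (1.00) was just short of 2-fold.

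Lists of epidermal genes had low medians at 4 h, except for the moulting genes. Of 10 epidermal antimicrobial peptide genes, 5 were lower (median -0.99), among them nlp-26 (-1.94), nlp-27 (-1.11) and nlp-30 (-1.01). Of the 10, 8 were measured by probe sets open to cross-hybridisation, and without these the list was too small to be placed. Of 18 hedgehog-related genes, which encode secreted epidermal proteins, 6 were lower (median -0.57), including grd-10 (-1.84) and grd-14 (-1.52). Without a filter the median of this list was -0.02 relative to all genes, still below the random lists. Of 114 cuticle collagen genes, 17 were lower and 2 higher (median -0.25), with col-49 (-2.13), col-120 (-1.97) and col-109 (-1.76) on the lower side and dpy-14 (1.82) and dpy-17 (1.51) on the higher. The other probe set of col-109 had a ratio of -0.22. Of 16 moulting genes, 1 was higher, noah-1 (1.51), and their median was 0.29, above the random lists. That position was lost without a filter (percentile 89.3) and without probe sets open to cross-hybridisation (81.8).

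The intestine, fat synthesis and fasting response lists had medians within the random lists at 4 h. Of 21 intestine genes, 5 were lower (median -0.04), including the peptide transporter gene pept-1 (-2.22), the gut actin gene act-5 (-1.96), cbl-1 (-1.35) and pho-1, which was at least 5.73-fold lower. Of 21 fat synthesis genes, 4 were lower, among them acs-1 (-1.81), the elongase genes elo-5 (-1.82) and elo-6 (-1.54), and 1 was higher, the desaturase gene fat-3 (1.06). Of 9 hypoxia response genes, 2 were lower, cysl-2 (-1.79) and rhy-1 (-1.52), and their median was -0.31, below the random lists. Of 19 fasting response genes, 2 were lower, acdh-2 (-1.39) and cpt-4 (-1.08), 1 was higher, the lipase gene lipl-2 (1.46), and the median was 0.00. Medians below the random lists were also found for the 18 V-ATPase genes (-0.18), the 28 body wall muscle genes (-0.10), the 23 major sperm protein genes (-0.49) and the 11 other sperm genes (-0.50). Medians above them were found for the 23 FMRFamide-like peptide genes (0.25), the 33 proteasome genes (0.10), the 74 ribosomal protein genes (0.06) and the 13 reference genes (0.20). Without probe sets open to cross-hybridisation the proteasome (percentile 44.6), reference (77.9) and hypoxia (3.3) lists lay within the random lists. With the mean of a gene's probe sets the ribosomal list (88.8) did so too, and with a filter at the 75th percentile the other sperm (6.6) and hypoxia (7.4) lists and the FMRFamide-like peptide list, with a median of 0.16 relative to all genes.

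Across the 44 lists, 6 had a median above and 11 a median below the central 95% of random lists at 4 h. If the members of each list varied independently, 2.2 lists would lie outside. Related genes and probe sets that share signal need not do so, and the number outside without any effect was not measured. Of the 17 lists outside, 9 kept their side under every alternative in which they were measured. When the arrays were scaled on the bacterial hybridisation controls instead, the median of all genes was 0.43 on the log2 scale, because the 9 control probe sets had a mean ratio of -0.45 (SD 0.14). The counts were then 545 higher and 122 lower, 81.7% higher against 34.5% as deposited, and of 86 detoxification enzyme genes 18 were lower and 14 higher. Under that scaling the medians of the collagen, cytochrome P450, glutathione S-transferase, hypoxia, V-ATPase and body wall muscle lists turned above 0, so all directions given are relative to the other genes of the array. The poly-A controls, transcripts added to the RNA before labelling, shifted by more (mean ratio -0.83), and no scaling on them was run.

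The comparison of 24 h with 0 h asked which transcripts differed after a day of exposure. Of 34 sperm genes in 2 lists, 29 were lower, as were 38 of 114 cuticle collagen genes, with 6 higher. Of the other lists, 6 of 16 moulting genes and 8 of 23 FMRFamide-like peptide genes were higher. All 23 major sperm protein genes, which encode the cytoskeletal protein of nematode sperm, were lower, with a median log2 ratio of -2.92. The probe sets used for them are all open to cross-hybridisation between near-identical copies. The detoxification gene cyp-35C1 was at 333.4 against 9296 (-4.67). On the higher side, mtre-1 was at 2109 against 49.7, at least 21.5-fold higher.

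At 24 h, 459 genes were higher and 687 lower than at 0 h. With the dimmest passing probe set of each gene in place of the brightest, 526 were higher and 637 lower. The 10 highest genes included the small heat shock gene hsp-12.6 (log2 ratio 3.98), Y110A2AL.4 (4.09), C32F10.4 (3.77), scl-2 (3.56), the C-type lectin gene clec-61 (at least 7.06-fold) and the cuticlin gene cut-3 (at least 8.19-fold). The 10 lowest included cyp-35A3 (-4.49), spig-20 (-4.46), cpg-9 (-4.16), ugt-13 (-3.97), the immune response gene irg-8 (-3.84), the folate transporter gene folt-2 (-3.63) and cyp-35A4, which was at least 13.2-fold lower. The metallothionein gene mtl-1 was still higher, at 2108 (3.36), and ftn-1, at 1300.0, was nearer its 0 h level (1.27).

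**Figure D1:**
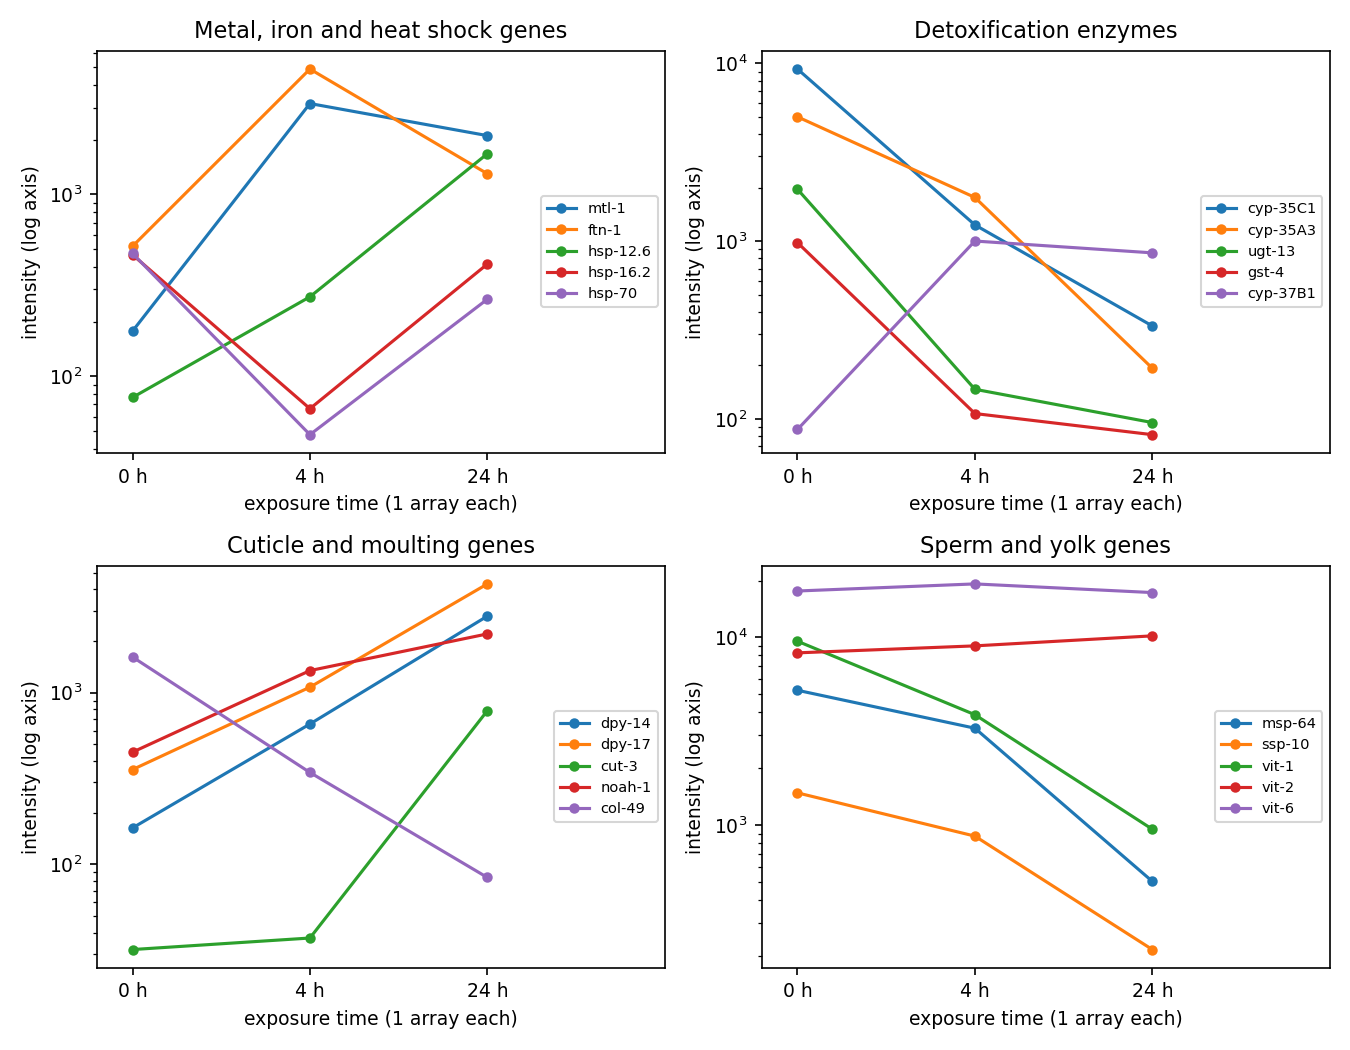
Intensities of 20 genes named in the text at 0 h, 4 h and 24 h (1 array each, log axis), in 4 panels by function, with 1 line per gene. mtl-1 goes from 177 to 3165 and 2108, and cyp-35C1 from 9296 to 1234 and 333.4.

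Both sperm lists had medians below the random lists at 24 h, and the other reproductive lists lay within them. Of 11 other sperm genes, 6 were lower and 0 higher (median -1.43, or -1.33 with values under the floor set to it), including ssp-16 (-2.69), ssp-10 (-2.60) and the sperm phosphatase genes gsp-3 (-2.42) and gsp-4 (-1.97). With a filter at the 75th percentile the median of that list was -0.42 relative to all genes and lay within the random lists. Among the msp genes, msp-64 was at 501.6 against 5215 and msp-142 at 381.4 against 3970 at 0 h. Of 26 oocyte and maternal genes, 2 were lower, mex-3 (-1.02) and puf-11 (-1.01), and the median was 0.00. None of 24 germline proliferation and meiosis genes passed 2-fold (median -0.05). Of 5 yolk protein genes, 1 was lower, vit-1, at 950.2 against 9514 (-3.28), while vit-2 (0.30), vit-5 (-0.20) and vit-6 (-0.03) lay near their 0 h level. The zygotic embryo list had 2 of 11 genes higher (median 0.14), hch-1, which encodes the hatching enzyme (2.24), and ceh-22 (at least 2.23-fold).

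Cuticle genes went both ways at 24 h. Of 114 collagen genes, 38 were lower and 6 higher, and the median was -0.68. Lower members were col-49 (-3.83), col-60 (-3.78) and col-120, which was at least 5.66-fold lower. Higher members were dpy-14, at 2792 against 162.8 (3.86), dpy-17 (3.48), col-165 (3.53) and col-74 (3.29). Of 16 moulting genes, 6 were higher and 0 lower (median 0.84), including noah-1 (2.21), the protease inhibitor gene mlt-11 (2.00), noah-2 (1.53) and nhr-25, a nuclear receptor gene of the moulting cycle (1.32). Of 10 epidermal antimicrobial peptide genes, 5 were lower (median -0.94), among them nlp-26 (-2.29), nlp-33 (-1.47) and nlp-27 (-1.35). Of 18 hedgehog-related genes, 4 were lower, including grd-3 (-2.85) and grd-5 (-2.73), and 2 were higher, including wrt-1 (1.36), with a median of 0.00.

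Neuronal and chromatin genes had medians above the random lists. All 23 FMRFamide-like peptide genes had a ratio above 0 at 24 h, 8 of them were higher, and the median was 0.81. Examples are flp-10 (1.79), flp-3 (1.40) and flp-12 (1.36). Of 19 neuron genes, 2 were higher (median 0.47), the neuropeptide-processing gene egl-21 (1.39) and the synaptic gene ric-4 (1.31). Of 30 histone genes, 3 were higher (median 0.20), the linker histone genes hil-1 (2.90) and hil-7 (2.80) and the variant his-71 (1.04). Without probe sets open to cross-hybridisation the histone list lay within the random lists (percentile 96.5). The 74 ribosomal protein genes had a median of 0.13, with rps-7, at 11715 against 5436, past 2-fold. Under quantile normalization their median was 0.08 and within the random lists (percentile 85.4). The brighter of a gene's probe sets had lower ratios than the dimmer at 24 h, with a mean difference of -0.35 over 1830 genes (SE 0.013). In the same array the 5' to 3' signal ratios of 4 of 4 control transcripts were higher than at 0 h, by a median of 0.56 on the log2 scale. For GAPDH the ratio was 0.382 at 0 h, 0.451 at 4 h and 0.579 at 24 h.

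Lists of detoxification genes were low at 24 h as well, with the cytochrome P450 median now within the random lists. Of 37 UDP-glycosyltransferase genes, 16 were lower and 1 higher (median -0.90), with ugt-8 (-3.33) and ugt-22 (-3.23) low and ugt-63 at least 5.65-fold lower. Of 23 glutathione S-transferase genes, 7 were lower and 3 higher (median -0.27), with gst-4 (-3.16) and gst-26 (-2.73) low and gstk-2 (1.60) and gst-20 (1.45) high. Of 27 cytochrome P450 genes, 6 were lower and 3 higher (median -0.15), the lower ones including cyp-35A2 (-3.58) and cyp-35B2 (-2.01). Of 23 oxidative stress genes, 6 were lower, including skn-1, a regulator of detoxification (-1.32), and 2 were higher, the superoxide dismutase gene sod-4 (1.33) and gcs-1, for glutathione synthesis (1.09). Among 26 ABC transporter genes 3 were lower, including pmp-5 (-2.09), and among 14 metal response genes 2 were higher, mtl-1 and ftn-1, and 1 was lower, cdr-4 (-2.83).

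The defence lists included members in both directions. Of 8 lysozyme genes, 4 were lower and 1 higher (median -0.71), with ilys-5, at 2588 against 14959 (-2.52), lys-4 (-1.90) and lys-2 (-1.33) low and ilys-3 (1.46) high. Of these 8 genes, 4 were measured by probe sets open to cross-hybridisation, and without such probe sets the median over the fewer genes left was 0.48. Without a filter the lysozyme list lay within the random lists (percentile 13.4). Of 12 saposin-like genes, 3 were lower and 3 higher (median 0.43), with spp-4 (-2.81) low and spp-8 (2.36) and spp-31, at 797.8 against 114.2, high. Of 51 C-type lectin genes, 9 were higher and 12 lower (median 0.06), and of 17 pathogen response genes, 1 was higher and 5 were lower, including irg-5 (-2.46) and irg-4 (-2.37). Of 21 intestine genes, 5 were lower and 0 higher (median -0.53), including pho-1 (-2.03), act-5 (-1.69) and the fatty acid binding protein gene lbp-6 (-1.50). The position of that list below the random lists was lost with a filter at the 75th percentile (22.1). Of 21 lysosomal protease genes, 7 were lower, such as asp-12 (-2.01), and 3 higher, such as cpr-2 (3.13).

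Of 21 fat synthesis genes, 3 were higher and 6 lower, and the median of -0.23 lay within the random lists. The desaturase genes fat-3, at 10158 against 1736 (2.53), and fat-4 (2.07) were higher, while fat-7 (-1.83) and fat-5 (-1.35), which make monounsaturated fat, and the elongase genes elo-6 (-2.59) and elo-5 (-2.54) were lower. Of 19 fasting response genes, 1 was higher, lipl-2 (1.42), and 5 were lower, including acdh-2 (-2.40) and hacd-1 (-1.75). Of 38 central carbon metabolism genes, 2 were lower, fbp-1 (-1.24) and mdh-2 (-1.15). Of 39 respiratory chain genes, 2 were higher, ucr-2.1, at 3045 against 1303, and atp-3 (1.15).

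Stress lists other than these had medians within the random lists at 24 h. Of 17 heat shock genes, 2 were higher, hsp-12.6 and hsp-12.3 (1.25). Of 18 DAF-16 target genes, 6 were higher and 2 lower (median 0.20), the lower ones being far-3 (-2.73) and fat-5. Of 21 endoplasmic reticulum unfolded protein response genes, 1 was higher, the chaperone gene enpl-1 (1.12), and of 14 mitochondrial ones 2 were lower, skn-1 and ubl-5 (-1.04). Of 16 osmotic stress genes, 2 were higher, hmit-1.3 (1.61) and aqp-2 (1.45), and of 9 hypoxia response genes 1 was lower, cysl-2 (-1.22). Of 23 DNA damage and apoptosis genes, 2 were higher, cps-6 (1.78) and ape-1 (1.31), and 1 was lower, xpa-1 (-1.03). Of 32 endocytosis and engulfment genes, 1 was higher, lgg-1 (1.01), and 2 were lower, rme-8, at 346.1 against 778.6, and rme-1 (-1.03). Of 79 nuclear hormone receptor genes, 5 were higher and 2 lower, nhr-114 (-2.06) and nhr-137 (-1.56), and of 48 F-box genes 3 were higher and 2 lower. None of the 33 proteasome, 18 V-ATPase, 28 body wall muscle or 13 reference genes passed 2-fold.

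**Figure D2:**
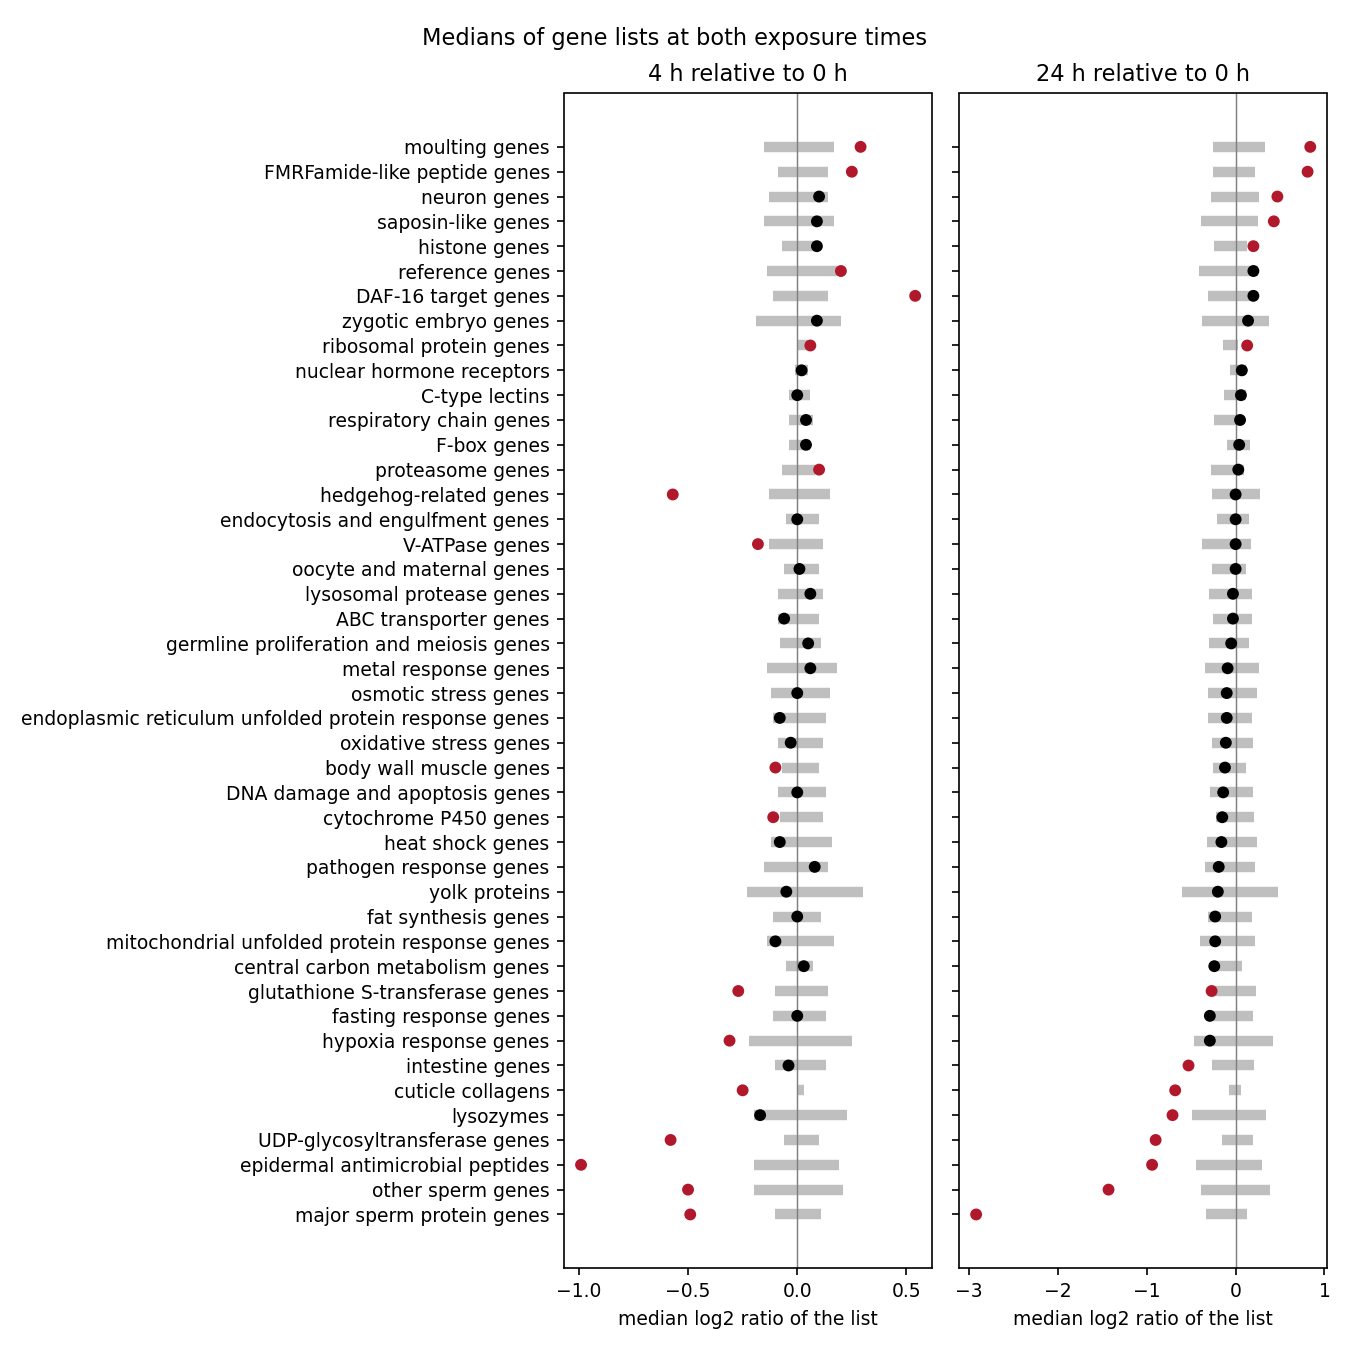
Median log2 ratios of the 44 gene lists at 4 h (left) and 24 h (right) relative to 0 h, 1 dot per list, red where the median lies outside the central 95% of 10000 random lists (grey bars). The major sperm protein genes lie lowest at 24 h (-2.92), and the moulting (0.84) and FMRFamide-like peptide genes (0.81) lie at the upper end, directions that were the same under the 4 other scalings.

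At 24 h, 6 of the 44 lists lay above and 8 below the random lists, and 9 of these 14 kept their side under every alternative in which they were measured. Hybridisation control scaling moved the median of all genes to 0.61 and the counts to 1896 higher and 318 lower, 85.6% higher against 40.1% as deposited. It turned the medians of the glutathione S-transferase and intestine lists above 0 and left those of the collagen and lysozyme lists at -0.06 each. Probe sets of the same gene differed by more at 24 h than at 4 h: the technical SD of a single log2 ratio was 0.47 for 24 h against 0 h, 0.24 for 4 h against 0 h and 0.29 for 24 h against 4 h. Of 183 genes past 2-fold at 24 h that had other probe sets, 151 had all of them in the same direction and 70 had all of them past 2-fold in it, and 0 had another past 2-fold in the opposite direction. The dimmer probe sets of mex-3 (0.05) and rme-8 (0.57) did not share the direction of the brighter, and that of enpl-1 had a ratio of 0.02. Many named genes rest on probe sets open to cross-hybridisation. Among the 10 highest and 10 lowest genes at 4 h these were ftn-1, fmo-1, cyp-35C1, Y16B4A.2 and hsp-70. Among those at 24 h they were mtre-1, Y110A2AL.4, C32F10.4, cut-3, clec-61, cyp-35C1, cpg-9 and folt-2. Other named genes, such as T13F3.6, cdr-4, elo-5, elo-6 and act-5, rest on such probe sets too.

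The comparison of 24 h with 4 h asked what differed between the early and the later exposure time. At the higher end were mtre-1 (log2 ratio 4.17) and 3 cuticle genes, col-165 (3.46), cut-3 (at least 8.19-fold) and col-74 (at least 10.5-fold), together with C54C8.12 (at least 7.07-fold). On the lower side were spig-20 (-3.30), cyp-35A3, at 192.8 against 1762, T13F3.6, at 345.8 against 2979.6, cyp-35A2 (-2.79) and msp-50 (-2.72). All 23 major sperm protein genes were lower at 24 h than at 4 h, for example msp-152 (-2.72) and msp-64 (-2.63).

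From 4 h to 24 h, 197 genes were higher and 278 lower. Hedgehog-related genes, low at 4 h, had 4 of 18 members higher and 2 lower (median 0.38), with wrt-1 (1.73), grl-7 (1.51) and grd-10 (1.44) among the higher. With the filter at the 75th percentile, which left fewer members, their median was -1.58. Without probe sets open to cross-hybridisation they lay within the random lists (percentile 92.2). The V-ATPase median was 0.24 and the DAF-16 target median -0.37, with ftn-1 (-1.89) and far-3 (-1.75) lower and hsp-12.6 (2.48) higher. Both lists lay within the random lists without probe sets open to cross-hybridisation (percentiles 89.8 and 8.2). The heat shock genes hsp-16.2, hsp-70 and hsp-16.41 were at least 4.47-fold, 2.98-fold and 2.49-fold higher than at 4 h. The nuclear receptor genes nhr-17 (2.21) and nhr-3 (2.12) were lower at 4 h than at 0 h (-1.60 and -1.15) and then above their 0 h level at 24 h (0.62 and 0.97). Of the 44 lists, 10 lay above and 7 below the random lists, and 7 of these 17 kept their side under every alternative in which they were measured. Hybridisation control scaling gave 340 higher and 223 lower genes, 60.4% higher against 41.5% as deposited, with a median of all genes of 0.19.

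Many genes were past 2-fold at both times. Of the 148 genes higher at 4 h, 104 were also higher at 24 h, and of the 281 lower at 4 h, 187 were also lower at 24 h. Independent lists of these sizes would share 7.87 and 22.4 genes. Both comparisons use the same 0 h array. Unchanged arrays simulated against it with the technical SD of each comparison shared 0.11 genes in either direction, since 0.11 genes per direction passed 2-fold at 4 h. The technical SD leaves out differences between animals, cultures and hybridisations, so these simulations give no error rate for unchanged worms. With the larger SD of 0.47 in both comparisons, simulated lists of 142 to 147 genes shared 22.8 higher and 22.6 lower. Of the simulated lists, just the one of genes higher at 4 h with the larger SD (147) was near the observed size (148). Part of the excess may come from the shared array. No gene was higher at 4 h and lower at 24 h. Counting genes past 2-fold at a single time and within 1.5-fold of 0 h at the other, 16 were higher and 39 lower at 4 h, and 190 were higher and 247 lower at 24 h.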

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

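The tests in this part were chosen after the results were seen, except the one on apical matrix genes. A single gene passed 2-fold in opposite directions at the 2 times: the uncharacterised gene R02F11.1 was at 332.4 at 0 h, 145.9 at 4 h and 959.2 at 24 h (log2 ratios -1.03 and 1.44). It was picked out after its values were seen, its probe set is open to cross-hybridisation, and the difference between the times was not tested. Probe sets without a listed gene were not part of the comparisons. Of the 182 that passed the filter, 2 were at least 2-fold higher and 3 lower at 4 h, and 7 were higher and 6 lower at 24 h, each relative to the 0 h array. Of 367 passing probe sets annotated to several genes, 4 were higher and 28 lower at 4 h, and 16 were higher and 73 lower at 24 h.

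The low level of sperm genes at 24 h is a pattern to follow up, with 29 of 34 genes of both sperm lists at least 2-fold lower. For the major sperm protein genes, signal from near-identical copies cannot be told apart from that of each gene, since just 1 of the 23, msp-32 (-1.22), had a passing probe set not open to cross-hybridisation. For the other sperm genes, probe sets marked as open to it are not the whole account. The 6 members measured by unmarked ones lay at percentile 0.22 of the random lists (median -1.08). Of these 6, 3 were at least 2-fold lower, and ratios ran from -2.69 to -0.01. Of the members of both lists, 85.3% were lower by more than 1.22, the 95th percentile of the difference between probe sets of the same gene. This gives the size of the fall and is no separate test of the RNA quality trend. The pattern was picked after its ratios were seen, and the signals of its 23 msp genes cannot be told apart. The hybridisation controls shifted by less (mean ratio -0.66) than the sperm genes (median -2.58). Scaling on these controls, with a median of all genes of 0.61, thus had to leave the sperm median low. It was -1.93, with 28 of 34 at least 2-fold lower, and the 23 msp genes largely set this median. For the other sperm genes alone the median under this scaling was -0.96, short of 2-fold. A scaling error of the size of the hybridisation control shift is thus not the whole account of the msp signal. For the other sperm genes it could account for part of the fall. The poly-A controls shifted by more at 24 h, and no scaling on them was run. A scaling error of that larger size was therefore not tested for the sperm genes. Whether the passage from sperm to oocyte production with age or the exposure lowered these transcripts cannot be told apart, since the number of later arrays without nanotubes is 0 (time or exposure).

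The higher level of moulting genes at 24 h may have a technical part. The median of the list was 0.84 as deposited and lay between 0.80 and 1.46 under 4 other scalings, none of which could have lowered it much. The RNA quality trend cannot be told apart from a change of these transcripts, since the probe positions are not known. Of the 16 members, 25% exceeded the 1.22 bound, which is no separate test of that trend. RNA of embryos or larvae held in the adults stays open as well: 7 of the apical matrix and epidermal genes of embryos and larvae were measured, and their median of 0.18 lay at percentile 84.08, between what that source and its absence would give. The most abundant of them, egg-6 and lin-26, at 3656 and 3298 at 0 h, had ratios of -0.85 and 0.00, while lpr-3 had 1.42; lin-26 and elt-3 are also in the zygotic embryo list, and all 7 gave signal at 0 h.

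The low level of detoxification enzymes at 4 h covers 23 of 87 genes of 3 lists, with 7 higher (median -0.32). Probe sets marked as open to cross-hybridisation do not account for their place below other genes. The 63 members measured by unmarked ones lay at percentile 0.00 of the random lists. Most members had unmarked probe sets from the start, and signal shared between unmarked probe sets of related genes was not tested. The direction is relative to other genes, and under the hybridisation control scaling, where the median of all genes was 0.43, that of the lists was 0.06, with 18 lower and 14 higher. Of the members, 36.8% were lower by more than 0.66, the 95th percentile of the difference between probe sets of the same gene at 4 h. The bound is for differences between probe sets, while the share counts single ratios on the lower side. The pattern was also picked after these ratios were seen, so the share is no separate test of the RNA quality trend. That trend cannot be told apart from a change of these transcripts. Fasting in the exposure medium could contribute, and the 19 fasting response genes lay at percentile 43.27 with 9 above and 9 below 0, which decides nothing. The exposure and the time in the medium vary together in these arrays, and any time without food would vary with them.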

How the results depend on the processing

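The hybridisation control scaling, the dimmest probe sets and the counts without sperm and collagen genes were chosen after the data were seen. Of 90 counts under the alternatives, 63 lay within 1.5 times the reported count. In the order higher and lower at 4 h against 0 h, at 24 h against 0 h and at 24 h against 4 h, a 1.5-fold threshold gave 531, 722, 1244, 1495, 591 and 798 genes, and a 3-fold threshold 45, 86, 134, 319, 52 and 122, by construction. A filter at the 75th percentile, with fewer genes tested, gave 71, 112, 224, 316, 76 and 139. Without _x_ and _s_ probe sets, again with fewer genes, 426 were lower at 24 h than at 0 h, and 131 were higher and 145 lower at 24 h than at 4 h. A pseudocount of 100 gave 128 genes higher at 24 h than at 4 h. The hybridisation control scaling, which shifts all genes up, gave 545 and 122 at 4 h, 1896 and 318 at 24 h and 340 higher at 24 h than at 4 h, and 270 of the 429 genes called at 4 h and 777 of the 1146 called at 24 h kept their call. Under quantile normalization, 416 of 429 and 1101 of 1146 did. Of 17, 14 and 17 lists outside the random range in the 3 comparisons, 9, 9 and 7 kept their side under every alternative in which they were measured. Without _x_ and _s_ probe sets, 11 of 15, 10 of 12 and 10 of 16 did. List medians, taken relative to all genes, moved by less than the technical SD in 549 of 571 values for lists outside the random range. That SD is of a single gene's ratio (0.24, 0.47 and 0.29 in the 3 comparisons) and exceeds several of these medians. Such a list could reach 0 and still count, as the cytochrome P450 list did at 4 h without a filter (-0.11 to 0.00). Medians relative to all genes also leave out the shift of the hybridisation control scaling. The values that moved by more follow, and for them the cause was not tested. Without a filter the medians were 0.03 for moulting, -0.02 for hedgehog-related, -0.29 for UDP-glycosyltransferase and -0.42 for epidermal antimicrobial peptide genes at 4 h. They were -0.56 for other sperm, -0.41 for UDP-glycosyltransferase and -0.01 for lysozyme genes at 24 h, and -0.19 for other sperm and 0.08 for hedgehog-related genes at 24 h against 4 h. At the 75th percentile filter they were 0.89 for moulting, -1.12 for hedgehog-related and -0.57 for glutathione S-transferase genes at 4 h, and -0.42 for other sperm and 2.03 for moulting genes at 24 h. At 24 h against 4 h they were -0.10 for other sperm, 0.74 for moulting and -0.63 for UDP-glycosyltransferase genes, and the hedgehog-related median reversed to -1.58. Without _x_ and _s_ probe sets the hedgehog-related median at 4 h was -0.85 and the lysozyme median at 24 h reversed to 0.48. Pseudocounts of 1 and 100 put the other sperm genes at -1.19 and -0.58 at 24 h against 4 h. Among named genes past 2-fold, mex-3 (0.03) and rme-8 (0.56) reversed with the dimmest probe set at 24 h, where enpl-1 was at 0.00, all relative to the median of all genes, and 2869 of 3063 stayed within the technical SD. Signal over background limits dim genes, where a value under the floor gives a bound.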

Other observations

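The families and the grouping in this part were chosen after the data were seen. Grouping the 8634 genes by the letters of their symbols gave 246 families of at least 5 genes, and in 9 of them at least 50% of the measured members passed 2-fold in the same direction at 4 h or 24 h, all on the lower side. Besides the msp, ssp and lys families, these were the lbp, hrg, ctsa, irg, msrp and abu families. Of 8 lbp genes, which encode fatty acid binding proteins, 5 were lower at 24 h (median log2 ratio -1.17), for example lbp-2 (-1.33), lbp-7 (-1.25) and lbp-3 (-1.22), while lbp-1 had a ratio of 0.91. Of 8 hrg genes, named for their response to heme, 4 were lower at 24 h (median -1.04), with hrg-7 at 340.5 against 2596 at 0 h (-2.82), hrg-11.2 (-2.05) and hrg-10 (-1.47). Of 6 ctsa genes, 3 were lower at 24 h (median -0.91), including ctsa-3.1 (-1.58). Of 6 irg genes, known from responses to infection, 3 were lower at 24 h (median -1.63). The msrp family had 5 of 7 genes lower (median -2.36).

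The abu genes, several of which are expressed in the pharynx, were low at 4 h. There, 6 of 7 were lower (median -1.59), including abu-14, at 424.3 against 1588 at 0 h (-1.83), and abu-10 (-1.71). At 24 h, 2 of 7 were lower (median -0.73), and abu-14 was at 2449 (0.62). Of the 7 genes, 5 were measured by probe sets open to cross-hybridisation.

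The poly-A control transcripts, added to the RNA before labelling, had a mean intensity 1.78-fold lower at 4 h and 2.29-fold lower at 24 h than at 0 h over 12 probe sets (SD 0.25 and 0.28 on the log2 scale). Controls for absent transcripts had mean ratios of -0.04 and 0.03 over 8 probe sets.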
